A study of Mus musculus with 32 samples.

How the data were processed

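Chromatin accessibility was measured by Omni-ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in mouse dendritic cell (DC) subsets sorted from skin-draining lymph nodes. The reads were processed and the peaks called by the authors. Per the submitters' processing notes the tools named are Bowtie2, deepTools and Genrich and the genome build is mm10; versions and settings are not given in the sources used here. How the read ends were shifted for the transposase's offset is likewise not given in the sources used here.

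The deposited files are 32 narrowPeak lists, 1 per library, so replicates were not pooled before peak calling. The peak signal that the authors deposited is never negative and has a minimum just above 200 in each list; it was used only to rank peaks within a list and to count peaks above a common value. The −log10 p value at each peak's summit, as deposited, served only to order peaks of equal signal. Since lists hold no read counts, the sequencing depth of each library is unknown, and no counting error, interval or detection limit can be given. A region missing from a list may be closed or may lie under the threshold of that list, and longer lists hold more weak peaks.

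Peaks on chromosomes 1 to 19 and X were used; no list had peaks on Y or the mitochondrial genome. Consensus regions were stretches of at least 100 bp covered by peaks of at least 3 of the 32 libraries. A region was called in a library when a peak overlapped at least 50% of the region or of the peak. There were 90465 regions with a median width of 569 bp. Each was assigned to a protein-coding gene of the mouse RefSeq table of assembly GRCm38.p6, whose coordinates are those of mm10: to the gene with an end within 1000 bp (15696 regions), otherwise to the gene body holding its midpoint (41896), otherwise to the nearest gene end within 50000 bp (24200, called distal). The other 8673 regions had no gene. The table gives no strand, so a gene end can be a promoter or a 3′ end; this took the place of the promoter rule fixed beforehand. Assignment by distance does not show which gene a region acts on.

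Groups came from the sample labels. Comparisons between subsets and between genotypes used the 28 libraries of the floxed cohort, and the 4 germline libraries were looked up, not tested. Per region, the number of libraries with a call was compared by an exact conditional test, two-sided, with genotype as strata for subset comparisons and subset as strata for the genotype comparison. Regions called in at least 3 and missing in at least 3 of the libraries compared were tested, and p-values were adjusted by the Benjamini-Hochberg method over all tested regions with a threshold of 0.05. A called difference therefore means a difference in how many libraries held a peak, not in signal height. The numbers of peaks per library and the Jaccard similarity of libraries (shared regions divided by regions called in either) were compared by exact permutation within the same strata.

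Lists of genes were fixed for 18 groups: the IFN-γ pathway, IFN-γ-induced genes, type I IFN genes, MHC class I presentation, MHC class II presentation, DC maturation and migration, tolerance-associated genes, cDC1 genes, cDC2 genes, Langerhans and skin DC genes, ubiquitously active genes, and markers of T cells, B cells, NK cells and ILC, monocytes and macrophages, neutrophils, plasmacytoid DC, and stromal and epithelial cells. The score of a list in a library is the percent of the list's regions that were called minus the percent of all assigned regions that were called, in percentage points. Scores were compared by exact permutation, two-sided, adjusted over the 18 lists. Enrichment of a list among called regions was tested one-sided against 10000 random gene sets matched gene by gene on the number of tested regions, capped at 40, and adjusted over lists and directions. No matching symbol was found for 4 listed genes (Gbp11, Cxcl11, Mx1, Mx2), and older symbols were matched through synonyms.

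Named genes followed a fixed rule. For each comparison it takes up to 20 list genes with called regions, ordered by the number of called regions in a direction, the size of the difference and the symbol, with at most 4 per list; up to 10 further genes of any kind per direction; and 20 genes that are always given, of which 1 is not reported here. Gene lists, groups, this rule, most tests and most of the alternatives were chosen before the data were examined. List enrichment in comparisons of single subsets, list scores between pairs of subsets and the test around Itgax were added after the data were seen.

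One alternative was equal list length, which kept the strongest peaks of each list. For region tests it kept as many as the shortest list of the comparison holds. For list scores and Jaccard similarity it kept 32649 peaks, the number in the shortest list of all libraries, a germline one. These scores therefore rest on shorter lists than the region tests, where the number was 54657 for DN migDC against migDC2. Further alternatives were the stronger part of each list above its own median signal, an overlap of 1 bp and a peak summit in the region. Others were fixed bins of 500 bp, no filter on tested regions, gene-end regions only and leaving out each library in turn. Title number as a block and restriction by genotype or by title series were also used. Title series matters because sample titles come as plain numbered and as lettered ones, which may be batches: all 12 resident libraries, 2 migDC2 and 2 DN migDC libraries have plain numbered titles, and the other 12 floxed migratory libraries have lettered titles.

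The tests were tested on simulated calls. With calls drawn so that 200 regions shifted from 0% to 100%, from 10% to 90% or from 25% to 75% of libraries, the migratory against resident test recovered 200, 147 and 16 of the 200, and the genotype test 200, 136 and 12. These sets were planted together in the same simulated calls, which makes the adjustment easier to pass than with fewer changed regions. The smallest p that the exact genotype test allows is 2.08e-06. Over 61445 tested regions, a fully separated region cannot pass on its own at that p. In the 5 comparisons of single subsets no such region was recovered, because the smallest p the design allows passes the adjustment only when many regions change; with 5571 regions fully changed the test of DN migDC against migDC2 recovered all 5571, and with 5246 changed that of migDC1 against migDC2 recovered 0. A list score raised by 10 percentage points was found in 20 of 20 simulations in both comparisons, and unchanged lists passed an unadjusted 0.05 in 1 of 20 (migratory against resident) and 2 of 20 (genotype). Of 50 random gene lists, 1 passed the enrichment test unadjusted for regions called more often and 0 for those called less often, against 41 of 50 lists seeded with changed genes.

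Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Transcription factor motifs were not analysed here because no genome sequence was used.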

Results

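Accessible chromatin was mapped in 32 libraries of dendritic cells (DC) from the skin-draining lymph nodes of mice. Conventional DC that reside in the node were sorted as cDC1, the lineage specialised in cross-presentation, and cDC2, the lineage marked by CD11b. Cells that had migrated from the skin were sorted as migDC1, migDC2 and DN migDC, the last being double negative for the markers that separate the other migratory subsets. Each subset came from mice with floxed Ifngr1 alleles that either lacked or carried a Cre recombinase driven by the CD11c promoter (Cre-negative and Cre-positive), and migDC2 came also from wild-type (WT) and germline Ifngr1 knockout (KO) mice. Ifngr1 encodes the ligand-binding chain of the receptor for interferon-γ (IFN-γ). The study asked whether signalling through this receptor shapes the chromatin of DC as they mature. There were 3 libraries per genotype of cDC1, cDC2, migDC2 and DN migDC, 2 per genotype of migDC1 and 2 per genotype of the germline migDC2. The labels do not say that replicates, or the subsets of a genotype, came from separate animals. The p-values therefore measure the spread between these samples, which may be technical, and take libraries of different subsets as independent.

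Peak lists held 32705 to 75106 peaks (median 58610.5) covering 22.939 to 53.119 Mb. Germline libraries had 32705 to 42499 peaks and floxed ones 38571 to 75106. In the floxed cohort, Cre-positive libraries had 58039.6 ± 8895.3 peaks (SD, n = 14) and Cre-negative libraries 59206.7 ± 9943.3 (n = 14), a mean difference within subsets of -723.6 (exact permutation p = 0.796, two-sided). Migratory libraries had 61509.2 ± 7405.2 peaks (n = 16) and resident libraries 54775.2 ± 10400.8 (n = 12), a difference of 6734.0 (exact permutation p = 0.0602, two-sided). That p fell under the threshold when 1 of 6 libraries was left out. These were cDC1 Cre-positive 1 (8338.3, exact p = 0.018), cDC1 Cre-negative 1 (7675.2, p = 0.0389), 2 (7751.0, p = 0.0363) and 3 (7461.2, p = 0.0466), migDC1 Cre-negative 1 (7921.0, p = 0.0218) and migDC2 Cre-positive 2 (7208.7, p = 0.0499). The strongest peak of the list lay over Cd74, the invariant chain of MHC class II, in 11 of 12 resident and 8 of 20 migratory libraries. It lay over Ccr7, the receptor that guides DC to the node, in 8 of 20 migratory and 0 of 12 resident libraries.

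At the targeted gene, Ifngr1 (chromosome 10, 19591949 to 19610229, mm10), no difference in peaks between genotypes passed the test. Of 4 regions touching the gene, 2 were called in all 32 libraries, knockouts included: the gene end at 19591054 to 19592900 and a gene body region at 19594212 to 19595012. Cre-positive libraries had 2.79 ± 0.89 of the 4 regions (SD, n = 14) and Cre-negative libraries 2.57 ± 0.76 (n = 14; exact permutation p = 0.25, two-sided), and the germline KO and WT libraries had a mean of 2.0 each. A deletion inside the gene that leaves these regions in place would not appear in peak lists, so the locus checks nothing about the genotype labels. Between cell types the locus did change, with 7 of its 10 tested regions called less often in migratory than in resident libraries. The gene body region at 19596481 to 19597430 was called in 1 of 16 migratory and 11 of 12 resident libraries (exact test, adjusted p = 7.9e-05).

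Migratory DC differed from resident DC at genes of maturation, migration and the response to interferon. Regions of Ccl22, Cd40, Cd274, Fscn1 and Irf1 were open in 16 of 16 migratory libraries and in 0 of 12 resident ones. A region in Xcr1, the chemokine receptor of cDC1, was called in 0 of 16 migratory and 12 of 12 resident libraries. Of 61445 tested regions, 24643 passed: 15347 were called more often and 9296 less often in migratory libraries. At equal list length, where 36025 regions were tested, the split turned to 9856 more and 11695 less. Calls more frequent in migratory libraries thus made up 62.3% with the full lists and 45.7% with lists of equal length. In both, 12473 regions were called with the same direction and 1 with the opposite one.

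Genes of DC maturation and migration made up the group with the most regions that opened. Of 506 tested regions of the list, 245 rose and 25 fell, and 284 and 36 when adjusted over the list alone. Random genes with as many tested regions gave a mean of 148.0 that rose (one-sided permutation p = 0.0001, the smallest the draws can give; adjusted p = 0.0036). Among 46 genes tested, 30 had only regions that rose, 13 had regions of both directions, 1 had only regions that fell and 2 had none. Ankrd33b had 24 of 35 regions more often called (for example chromosome 15, 31355192 to 31355888, in its gene body), Mreg 20 of 32, Samsn1 20 of 26 and Spred1 13 of 19. Zfp366, whose product DC-SCRIPT is a DC transcription factor, belongs to the cDC1 list instead and had 18 of 24. Cd40, the receptor for T cell help, had 7 of 11 (chromosome 2, 165048847 to 165050138), and Cd83 5 of 12. Ccl22, a chemokine for CCR4-bearing T cells, had 5 of 8 (chromosome 8, 94735443 to 94736021), Fscn1, the actin-bundling fascin of mature DC, 3 of 5, and Relb 3 of 3. Ccr7 had 3 of 8 regions more often called, among them chromosome 11, 99178805 to 99179414, in 15 of 16 migratory and 1 of 12 resident libraries. Cd86, a costimulatory ligand, went mostly the other way, with 1 region more and 7 less often called of 19. The region at chromosome 16, 36594827 to 36596874 was called in 1 of 16 migratory and 12 of 12 resident libraries.

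Among interferon-related genes, those induced by IFN-γ had more rising than falling regions. Of 148 tested regions of IFN-γ-induced genes 53 rose and 14 fell, and 63 and 21 when adjusted over the list alone. Random genes had 35.3 rising regions (one-sided permutation, adjusted p = 0.0846). At equal list length 48 of 88 rose, against 23.2 in random genes (permutation, adjusted p = 0.0018). Of 39 genes tested, 17 had only rising regions, 10 only falling ones, 3 both and 9 neither. Cd274, encoding PD-L1, had 5 of 8 regions more often called (chromosome 19, 29394863 to 29395769). The MHC class I activator Nlrc5 had 8 of 13, and the MHC class II activator Ciita 4 of 12 with 1 less often called. The IFN-γ pathway list itself had 30 regions that rose and 11 that fell of 92 (31 and 14 adjusted over the list alone), with Jak2 at 7 of 16 more often called and Ifngr1 among those that fell. Type I IFN genes had 13 up and 6 down of 47, the same numbers adjusted over the list alone. Neither list passed for rising regions, with 23.7 and 10.1 of them in random genes (one-sided permutation, adjusted p = 0.744 and 0.792). Socs2 had 1 region more and 1 less often called of 6.

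MHC class I presentation genes had 19 regions that rose and 6 that fell of 58 (20 and 6 adjusted over the list alone), whereas MHC class II presentation genes had 8 and 7 of 54 (7 and 7). Tolerance-associated genes had 61 and 21 of 169 (72 and 25 adjusted over the list alone; random mean 44.0, permutation adjusted p = 0.148), led by Pdcd1lg2, encoding PD-L2, with 9 of 20 more often called, and by Il2ra with 7 of 10. The aryl hydrocarbon receptor gene Ahr had 8 of 15 less often called. Genes of the cDC1 list were split, 72 and 74 of 328 (82 and 98 adjusted over the list alone), and 29 of 52 regions at Wdfy4, which cross-presentation requires, were less often called. The 74 compare with 41.8 falling regions in random genes (one-sided permutation, adjusted p = 0.0864), and MHC class I genes had 14.3 rising ones in random genes (adjusted p = 0.744). Genes of the cDC2 list had 35 and 22 of 172 (35 and 20), and Langerhans and skin DC genes 39 and 22 of 134 (41 and 25), with Epcam at 6 more and 1 less of 8. Cd207, encoding langerin, had no region that passed, and the one with the smallest p was called in 15 of 16 migratory and 6 of 12 resident libraries (exact test, adjusted p = 0.0556). Irf8 had 6 regions more and 4 less often called of 26, Irf4 2 more of 12, Itgae 3 more and 1 less of 10, and Itgam 1 more and 6 less of 16.

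Among all genes, the most rising regions were at Atxn1 (34 of 52), Rftn1 (27 of 42), Septin9 (26 of 47), Etv6 (24 of 58) and Pard3b (23 of 28). After Wdfy4, the most falling regions were at Snx29 (17 of 50), Dennd4a (16 of 37), Camk1d (15 of 43), Sfi1 (15 of 16) and Sgms1 (15 of 37), and Pik3ap1 had 10 of 22. No list of markers of other cell types, nor that of ubiquitously active genes, passed the one-sided permutation test against random genes (smallest adjusted p = 0.744 for rising and 0.849 for falling regions, 0 lists at an unadjusted p under 0.05). B cell markers had 22 regions that rose and 2 that fell of 70, against 17.3 rising in random genes, and Pax5, a B cell transcription factor, gave 9 of them. Plasmacytoid DC markers had 25 and 6 of 82, with 15 at Runx2. T cell markers had 16 and 6 of 70 (15 and 5 adjusted over the list alone), against 17.0 rising in random genes, with 8 at Tcf7. NK and ILC markers had 15 and 5 of 44. Monocyte and macrophage markers had 19 and 8 of 79 (19 and 7). The transcription factor gene Zeb2, of the cDC2 list, had 9 regions that passed in the same direction. Neutrophil markers had 10 and 6 of 29 (10 and 9), stromal and epithelial markers 13 and 6 of 50, and ubiquitously active genes 9 and 10 of 58. Where no second pair is given, the list alone gave the same numbers.

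**Figure D1:**
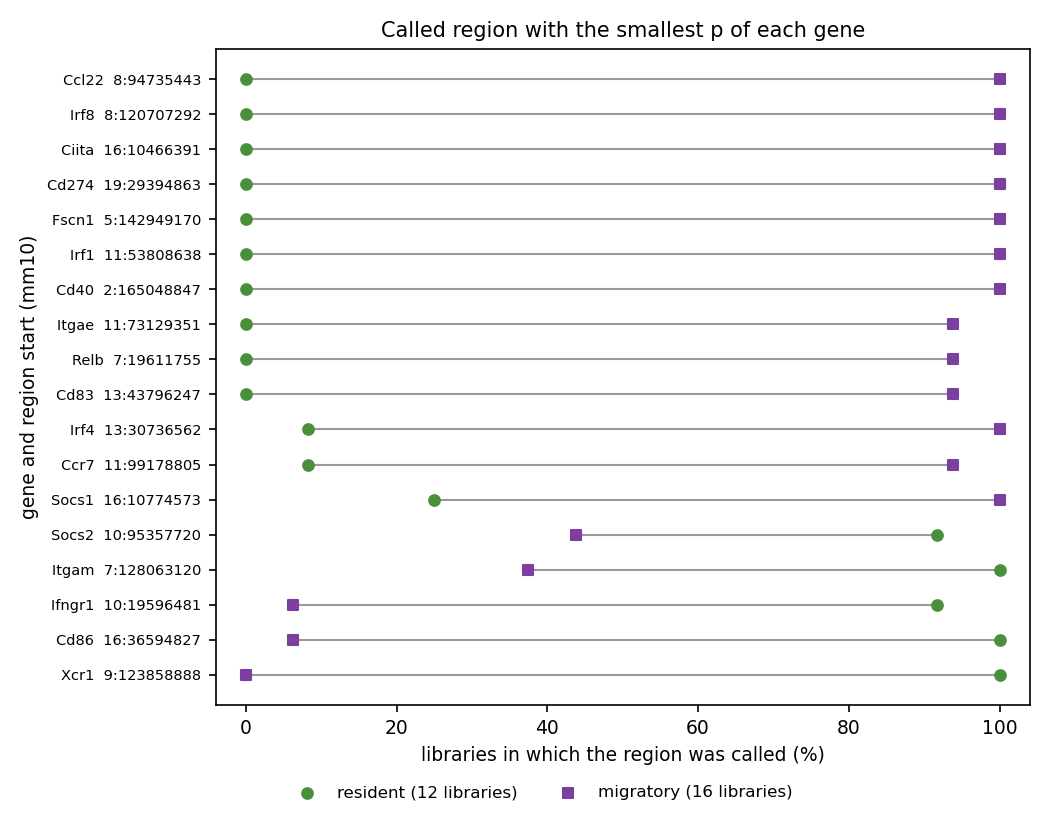
Percent of resident (green circles, 12 libraries) and migratory (purple squares, 16 libraries) libraries in which the called region with the smallest p of an always-given gene was found, with the region's start in mm10. The genes shown each have a region that passed. The regions of Cd40, Ccl22, Irf8, Irf1, Ciita, Cd274 and Fscn1 were called in 16 of 16 migratory and 0 of 12 resident libraries, and that of Xcr1 in 0 of 16 and 12 of 12.

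Scores of the gene lists per library, which set a list against all assigned regions, passed for 12 of 18 lists, where enrichment over random genes had passed for rising regions of maturation genes alone. The DC maturation score was 7.6 ± 3.14 percentage points in migratory libraries (SD, n = 16) and -14.76 ± 5.23 in resident ones (n = 12), an effect of 22.36. Scores of IFN-γ-induced genes were 7.64 ± 2.78 and -5.47 ± 2.33 (effect 13.1), and those of tolerance-associated genes 4.94 ± 2.9 and -6.35 ± 1.67 (effect 11.29). In all of these each migratory library lay above each resident one. MHC class II presentation genes scored 8.86 ± 2.79 in migratory and 18.11 ± 3.94 in resident libraries (effect -9.25), while the share of their regions called was 72.4% and 75.3%. Each of these 4 scores reached the smallest p the exact permutation allows (1.11e-07, two-sided; adjusted p = 4.99e-07). MHC class I presentation genes rose by 12.1 (exact test, adjusted p = 0.00062), Langerhans and skin DC genes by 5.02 (adjusted p = 3.19e-06), the IFN-γ pathway by 3.91 (adjusted p = 0.00239) and type I IFN genes by 5.47 (adjusted p = 0.0237). For type I IFN genes migDC1 minus cDC1 was 15.21 (exact permutation, adjusted p = 0.0164) and migDC2 minus cDC2 -1.01 (adjusted p = 0.624), and the difference between the lineages was not tested. Markers of B cells rose by 13.27 (exact test, adjusted p = 0.00198), and of NK cells and ILC by 11.59 and plasmacytoid DC by 12.18 (adjusted p = 9.23e-06 each). The score of ubiquitously active genes differed by -6.1 (exact test, adjusted p = 9.23e-06), while 68.9% of their regions were called in migratory and 68.7% in resident libraries, against 63.5% and 57.2% of all assigned regions. Effects of 3.35 for T cell, -2.39 for monocyte and macrophage, -3.78 for neutrophil and 1.8 for stromal and epithelial markers, and of -4.15 for cDC1 and -1.89 for cDC2 genes, did not pass. At equal list length the effects shrank to 2.38 for Langerhans and skin DC genes, 3.07 for B cell, 3.45 for NK and ILC and 3.22 for plasmacytoid DC markers and -1.6 for ubiquitously active genes, all still past the exact test. T cell markers (4.16, adjusted p = 0.0138) and neutrophil markers (-3.99, adjusted p = 0.00681) passed the exact test there. Neutrophil markers also passed without the first Cre-positive cDC1 library (-4.77, exact test, adjusted p = 0.0325). With regions at gene ends only, B cell markers (3.76) and NK and ILC markers (5.69) did not pass. There the IFN-γ pathway (-0.35, exact p = 0.861) and ubiquitously active genes (2.18, exact p = 0.103) turned in direction without passing, and cDC2 genes (-12.29), monocyte and macrophage (11.59), neutrophil (-56.18) and stromal and epithelial markers (8.82) passed. Without the DN migDC libraries, an alternative chosen after seeing the data, the effect of B cell markers was 6.45 (exact test, adjusted p = 0.0199).

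**Figure D2:**
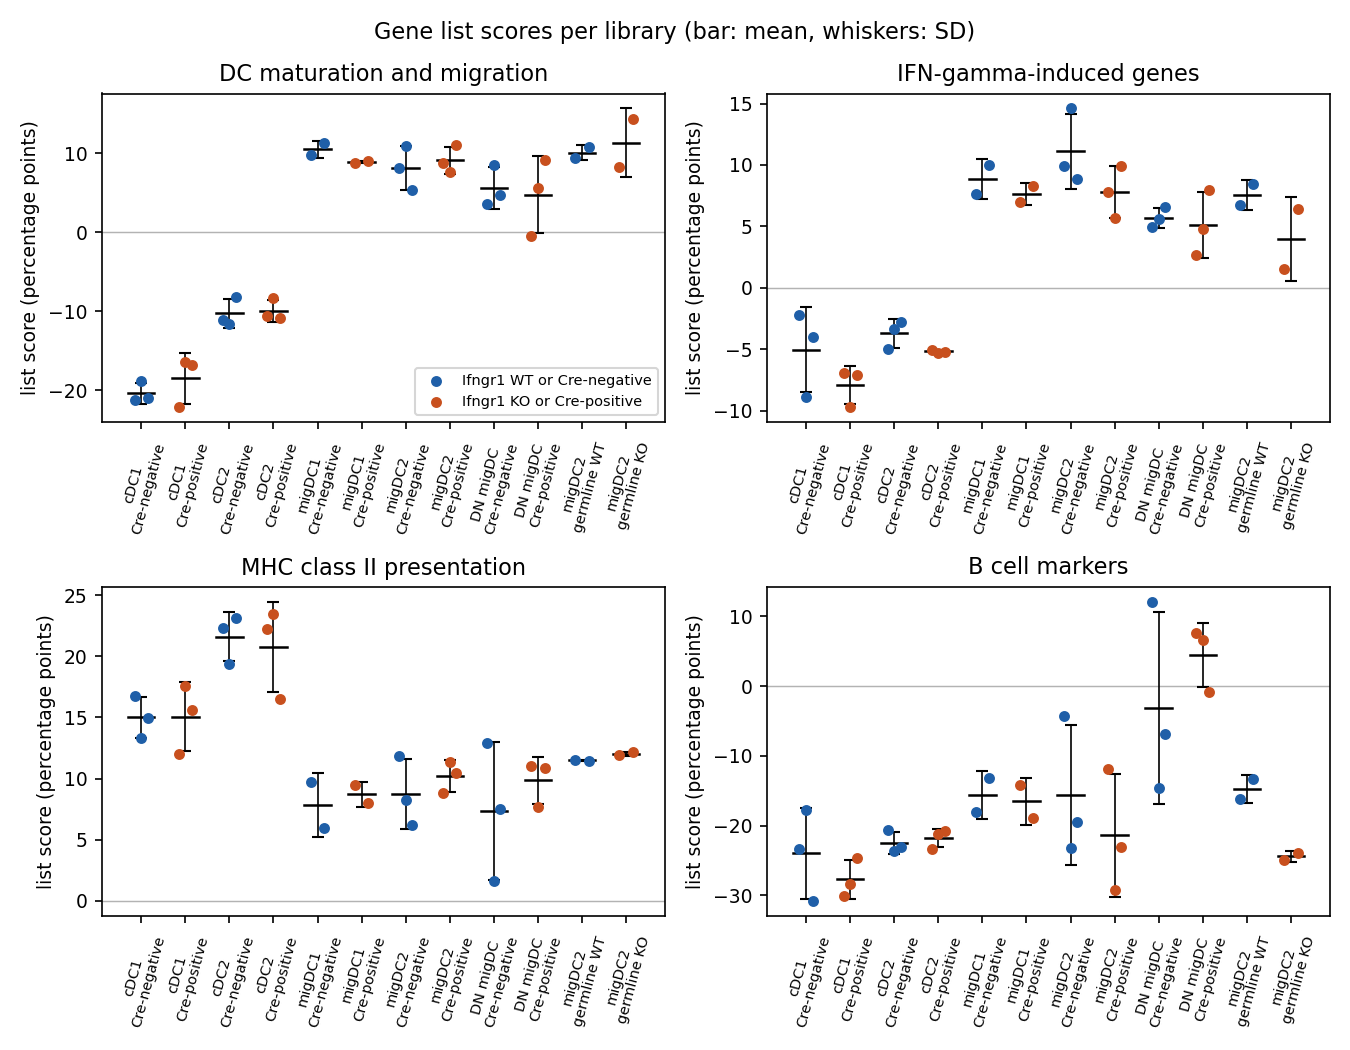
Score of 4 gene lists in each library (points), in percentage points, by subset and genotype, with the mean (bar) and SD (whiskers) of each group of 2 or 3 libraries. Maturation and IFN-γ-induced genes score higher in each migratory library than in each resident one, with 7.6 ± 3.14 against -14.76 ± 5.23 for maturation.

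The region test was an exact conditional test with genotype as strata, and 3212 regions were called in all 16 migratory and 0 of 12 resident libraries and 81 the other way round, which is the smallest p the design allows (1.11e-07). Within the plain numbered titles alone (4 migratory, 12 resident libraries) 10859 regions passed, 9774 more and 1085 less often called in migratory libraries. Of the 24643 regions, 98.0% of those more and 89.8% of those less often called differed in the same direction there, but these libraries had also entered their selection. Score effects within those titles were 19.75 for maturation, 11.81 for IFN-γ-induced, 8.94 for tolerance-associated, -6.95 for MHC class II, 25.25 for MHC class I and 24.87 for B cell genes. The IFN-γ pathway (2.93, exact p = 0.124) and type I IFN genes (4.24, exact p = 0.332) did not pass there. MHC class I scores of plain-titled migDC2 averaged 17.65 against -0.41 ± 2.41 in lettered ones (n = 4), and those of DN migDC 14.14 against -2.12 ± 4.58. The call for type I IFN genes was lost without the first Cre-negative cDC1 library (effect 4.36, exact test, adjusted p = 0.0558), the first Cre-positive cDC1 library (4.3, adjusted p = 0.0568) or the second Cre-positive cDC1 library (4.78, adjusted p = 0.0525).

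Between the resident subsets, many regions called in cDC1 were not called in cDC2. Irf8 (4 of 18 tested regions), Xcr1 (1 of 2, chromosome 9, 123861728 to 123862357), Itgae, Cadm1 (8 of 23), Wdfy4 (15 of 48), Rab7b (6 of 12) and Fgd6 (5 of 7) had regions called in 6 of 6 cDC1 and 0 of 6 cDC2 libraries. Regions of Sirpa, an inhibitory receptor that marks cDC2 (2 of 7), Irf4, a transcription factor of cDC2 (1 of 5), C5ar1 (3 of 3), Il1r2 (5 of 13), Fosl2 and Plaur were called in 6 of 6 cDC2 and 0 of 6 cDC1 libraries. Lists of cDC2 were shorter, with a mean of 46972.67 (Cre-negative) and 47521.67 (Cre-positive) peaks against 64874.33 and 59732.0 in cDC1. Of 31371 tested regions 4879 passed, 677 more and 4202 less often called in cDC2 (13.9% more). With lists of equal length 8100 of 17470 passed, 3625 more and 4475 less (44.8% more), and 2591 regions were called in both with the same direction.

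Genes of the cDC1 list had 66 falling and 0 rising regions of 219 in cDC2, and 111 and 1 when adjusted over the list alone. In random genes 39.1 fell (one-sided permutation, adjusted p = 0.0036), and 21 of 29 genes had a region that fell. Outside the cDC1 list, Kit, Dkk3 and Laptm4b had 3 falling regions each and the interleukin-12 subunit gene Il12b had 2. The cDC2 list had 5 rising and 10 falling regions of 97 (the same adjusted over the list alone), DC maturation genes 5 and 21 of 166 (the same), and monocyte and macrophage markers 4 and 6 of 44 (the same). Ahr, Ifngr1 and Vsir had 2 regions less often called each in cDC2, and Itgam and Cd207 1 each. Foxp1, Cdk14 and Camk1d led the falling regions outside the lists with 8 each, and App, Malt1 and Myo1e the rising ones with 4 each. In score comparisons added after the data were seen, 10 of 18 lists passed. Genes of the cDC1 list scored -15.57 ± 1.92 in cDC2 and 6.07 ± 2.72 in cDC1 (SD, n = 6 each). Genes of the cDC2 list scored higher in cDC2 by 6.47, type I IFN genes by 13.12, MHC class I genes by 11.36 and MHC class II genes by 6.14 (exact permutation, adjusted p = 0.0129 each and 0.02 for MHC class II). Maturation genes, at -10.1 against -19.41, and markers of monocytes and macrophages (11.55), plasmacytoid DC (9.57), neutrophils (9.27) and ubiquitously active genes (3.26) also scored higher in cDC2 (exact permutation, adjusted p at most 0.027). Scores are relative to all assigned regions, and fewer regions of any kind were called in cDC2. The mean was 49.0% (Cre-negative) and 49.57% (Cre-positive) of all regions, against 64.39% and 61.4% in cDC1. A higher score in cDC2 therefore does not mean that more regions of the list were called there. The neutrophil call was lost without the first (7.68) or second (9.34) Cre-negative cDC2 library (exact permutation, adjusted p = 0.054 each). MHC class I genes (2.69), neutrophil markers (2.2) and ubiquitously active genes (0.93) did not pass at equal list length. There the IFN-γ pathway (5.77), IFN-γ-induced genes (5.01) and tolerance-associated genes (3.72) passed instead, higher in cDC2 (exact permutation, adjusted p = 0.009 each).

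All 4879 calls separated the libraries completely, which has p = 0.005, the smallest the exact test allows with 6 against 6 libraries (adjusted p = 0.0321). The count was 12081 without the second Cre-negative cDC1 library, 12558 without the second Cre-positive cDC1 library and 0 by the exact test with bins of 500 bp, where 9359 bins had an unadjusted exact p under 0.05.

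Along the cDC2 lineage, many regions called in migDC2 were not called in cDC2. Ankrd33b (19 of 30 tested regions), Zfp366 (16 of 20), Samsn1 (15 of 20), Mreg (13 of 19), Irf1 (9 of 11), and Cd40 (7 of 8) had regions called more often. So did Il15, a cytokine presented to lymphocytes (7 of 7), Ccl22 (5 of 8), Cd274 (5 of 6), Ly75, encoding the endocytic receptor DEC-205 (6 of 7), and Relb (3 of 3). Il1r2, a decoy receptor for interleukin-1, lost the most, with 11 of 14 regions less often called, and 2 of 13 Cd86 regions, 2 of 5 Ifngr1 regions and 1 of 2 Xcr1 regions fell. Lists of migDC2 were longer, with a mean of 66025.67 (Cre-negative) and 60360.67 (Cre-positive) peaks against 46972.67 and 47521.67 in cDC2. Of 32756 tested regions 13511 passed, 12195 more and 1316 less often called (90.3% more). With lists of equal length 11199 of 20192 passed, 6393 more and 4806 less (57.1% more), and 5718 were called in both with the same direction.

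By list, DC maturation genes had 172 rising and 7 falling regions of 346 (random mean 151.8), with 36 of 45 genes having only rising regions. IFN-γ-induced genes had 46 and 0 of 98, in 18 of 34 genes, and tolerance-associated genes had 50 and 2 of 102. Counts adjusted over the list alone were the same for these 3 lists. No list was enriched by the permutation test over random genes at the full list length (smallest adjusted p = 0.703, with 1 list and direction under an unadjusted 0.05). Rising regions of IFN-γ-induced genes (30 of 54) and maturation genes (121 of 209) were enriched at equal list length (permutation, adjusted p = 0.0036 each). So were falling regions of MHC class II genes (16 of 26, permutation, adjusted p = 0.0048). Ciita, Itgae and Nlrc5 had 5 rising regions each, Irf8 4, Ccr7, Fscn1 and Irf4 2, and Cd83, Socs1, Socs2 and Cd207 1 each. Atxn1 (26), Rftn1 (24), Septin9 (23), Pard3b (21 of 21) and Sema6d (20) led outside the lists. Score comparisons added after the data were seen passed for 7 lists. These were maturation, 8.63 ± 2.14 against -10.1 ± 1.47 (SD, n = 6 each), IFN-γ-induced genes, 9.45 ± 2.97 against -4.45 ± 1.09, tolerance-associated genes (effect 12.25), MHC class II genes (9.49 against 21.18) and ubiquitously active genes (-6.25), each with an exact permutation adjusted p of 0.018. The others were Langerhans and skin DC genes (4.6, exact test, adjusted p = 0.03) and neutrophil markers (-10.87, adjusted p = 0.0386). The neutrophil call was lost without the first (-9.27, exact permutation, adjusted p = 0.0771) or second (-10.93, 0.0514) Cre-negative cDC2 library or the first Cre-negative migDC2 library (-9.9, 0.0563). Ubiquitously active genes did not pass at equal list length (-2.47, exact permutation, adjusted p = 0.123). The IFN-γ pathway (4.0, adjusted p = 0.0257), cDC1 genes (5.91, adjusted p = 0.018) and NK and ILC markers (2.98, adjusted p = 0.03) passed the exact permutation there.

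Complete separation of 6 and 6 libraries has p = 0.005 in this exact test (adjusted p = 0.0181); 8558 regions were called in all migDC2 and 0 cDC2 libraries and 514 the other way round. Within plain numbered titles there were 2 migDC2 and 6 cDC2 libraries, too few to pass (smallest exact p 0.125; 0 calls and 0 regions at an unadjusted p under 0.05, of 11842 tested).

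Along the cDC1 lineage, migDC1 gained and lost similar numbers of regions. Gains were at Zfp366 (13 of 21 tested regions), Mreg (12 of 20), Il12b (8 of 9), Il2ra (6 of 6), Samsn1 (6 of 12), Slco5a1 (6 of 10), Ly75 (5 of 9), Nlrc5 (5 of 9), the phagocytic receptor Mertk (4 of 6) and the antiviral gene Rsad2 (4 of 4). Losses were at Wdfy4 (16 of 40), Sfi1 (11 of 13), Fcgr3 (7 of 8), Rab7b (6 of 11), Cd86 (5 of 10), Ahr (5 of 13), Ifngr1 (4 of 8), Itgam (3 of 11) and Xcr1 (1 of 1). Of 36815 tested regions 12987 passed, 6806 more and 6181 less often called in migDC1 (52.4% more). With lists of equal length 12409 of 25970 passed, 7509 and 4900 (60.5% more), and 8496 were called in both with the same direction.

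DC maturation genes had 113 rising and 18 falling regions of 275 (the same adjusted over the list alone) against 55.5 rising in random genes (one-sided permutation, adjusted p = 0.0036). Type I IFN genes had 12 and 4 of 30 and tolerance-associated genes 35 and 13 of 100 (permutation adjusted p = 0.0576 each). IFN-γ-induced genes had 24 and 8 of 92, cDC1 genes 39 and 51 of 223, and MHC class II genes 3 and 10 of 34. Adjusted over the list alone, each of these lists had the same numbers. Irf1 had 3 rising regions, Ccl22, Fscn1 and Socs2 2 each, and Cd40, Cd274 and Relb 1 each. Ccr7 and Cd83 regions called in 3 of 4 migDC1 and 0 of 6 cDC1 libraries did not pass (exact test, adjusted p = 0.0839). Outside the lists Atxn1 (22 of 36) and Ralgapa2 (14 of 22) had the most rising regions. Score comparisons added after the data were seen passed for 12 lists. They include maturation (9.69 ± 1.12, n = 4, against -19.41 ± 2.43, n = 6), IFN-γ-induced genes (8.24 against -6.49), type I IFN genes (effect 15.21) and tolerance-associated genes (13.76). MHC class I (12.66) and class II (-6.76) genes, the IFN-γ pathway (6.72) and Langerhans and skin DC genes (5.26) also passed. So did markers of NK cells and ILC (15.85), plasmacytoid DC (14.66) and monocytes and macrophages (-9.97). Each of these had an exact permutation adjusted p of 0.0164, and B cell markers (9.77) had an exact adjusted p of 0.045. The B cell call was lost at equal list length (0.62) and without any 1 of 7 libraries. These were migDC1 Cre-negative 1 (10.98) and 2 (8.55), migDC1 Cre-positive 1 (8.58) and 2 (10.96), and cDC1 Cre-positive 1 (9.17), 2 (9.6) and 3 (10.52) (exact permutation, smallest adjusted p = 0.0692). The call for MHC class I genes was lost without the second Cre-positive migDC1 library (11.98, exact permutation, adjusted p = 0.075).

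The 4 migDC1 libraries all have lettered titles and the 6 cDC1 libraries plain numbered ones, so title series and migration cannot be told apart in any of these region counts and scores. With 4 and 6 libraries, complete separation gives p = 0.01, the smallest possible (exact test, adjusted p = 0.0283). Leaving out any 1 of the 4 migDC1 libraries raises that floor to 0.025 and ends the calls, with 0 passing the exact test. Of regions at an unadjusted exact p under 0.05, 15421 and 13776 were left without the first and second Cre-negative library, and 13603 and 13721 without the first and second Cre-positive one.

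Both lineages changed many of the same regions on migration. Of 17941 regions tested in both comparisons, which share no libraries, 4648 were called more often in migDC1 than cDC1 and in migDC2 than cDC2, where independent lists would share 2254.8. Another 483 were less often called in both, against 136.7, 0 rose in the cDC1 and fell in the cDC2 lineage, against 269.9, and 15 fell and rose, against 1142.2. Title series runs along both comparisons, as 4 of 4 migDC1 and 4 of 6 migDC2 libraries are lettered and the resident ones plain. The values for independent lists do not allow for that. Zfp366, Mreg, Samsn1, Il2ra, Runx2 and Atxn1 had rising regions in both lineages. With the full lists, which differ in length between subsets, mean Jaccard similarity was 0.619 between cDC1 and cDC2 and 0.69 between migDC1 and migDC2. It was 0.796, 0.782, 0.795, 0.822 and 0.783 within cDC1, cDC2, migDC1, migDC2 and DN migDC.

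Among migratory subsets, DN migDC and migDC2 were the most similar pair, with a mean Jaccard similarity of 0.769 against 0.693 for migDC1 and DN migDC and 0.69 for migDC1 and migDC2. Lists of migDC1 were shorter, with a mean of 52725.0 (Cre-negative) and 58210.5 (Cre-positive) peaks. Those of migDC2 had 66025.67 and 60360.67 peaks and those of DN migDC 63275.33 and 64430.33. All migDC1 libraries also have lettered titles, and these similarities allow for neither difference. Between DN migDC and migDC2, no region of 22285 passed the exact conditional test, and the smallest adjusted p was 0.324. There were 1377 regions at an unadjusted p under 0.05 (411 more and 966 less often called in DN migDC). A region near Ccl22 (chromosome 8, 94755815 to 94756643) was called in 0 of 6 DN migDC and 6 of 6 migDC2 libraries and one near Irf8 (chromosome 8, 120797052 to 120797812) in 6 and 0 (exact p = 0.005, the smallest possible). There were 74 and 246 regions called in all DN migDC and 0 migDC2 libraries and the reverse. In score comparisons added after the data were seen, tolerance-associated genes were lower in DN migDC (2.07 ± 2.41 against 6.72 ± 1.35, n = 6 each). Genes of the cDC2 list were lower (-4.17 ± 2.93 against 3.13 ± 2.79) and T cell markers were higher (-5.59 against -14.12; exact permutation, adjusted p = 0.03 each). All 3 calls were lost without the third Cre-positive migDC2 library (exact permutation, smallest adjusted p = 0.09) or the third Cre-negative DN migDC library (0.06). The call for tolerance-associated genes was also lost without the second Cre-negative (-4.5), first Cre-positive (-4.85) or second Cre-positive (-4.78) migDC2 library. That for T cell markers was lost without the second Cre-negative DN migDC library (8.87), and that for cDC2 genes without the first Cre-positive one (-6.65). At equal list length tolerance-associated genes (-4.18, exact permutation, adjusted p = 0.054) and T cell markers (4.27, adjusted p = 0.06) did not pass. The IFN-γ pathway (-4.52, adjusted p = 0.03), maturation genes (-4.07, adjusted p = 0.045) and monocyte and macrophage markers (-2.95, adjusted p = 0.03) passed the exact permutation there, lower in DN migDC. With title series as strata 4 of 18 lists passed at the full list length. With title series and genotype as strata 5 passed, against 3 with genotype alone.

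For migDC1 against migDC2, regions of Irf8 (chromosome 8, 120797052 to 120797812) and Xcr1 (chromosome 9, 123861728 to 123862357) were called in 4 of 4 migDC1 and 0 of 6 migDC2 libraries. Regions near Ccl22, Ccr7, Cd40, Cd83 and Irf1 were called in 0 of 4 and 6 of 6. None of 20987 regions passed the exact conditional test, 6400 had an unadjusted p under 0.05 (2358 more and 4042 less often called in migDC1), and complete separation reached an adjusted p of 0.0594. At equal list length, where fewer regions were tested, 3534 of 13487 passed, 2025 more and 1509 less often called. Scores of cDC1 genes were 3.35 ± 1.17 in migDC1 (n = 4) and -13.44 ± 1.83 in migDC2 (n = 6), and those of monocyte and macrophage markers -19.95 ± 1.01 and 0.8 ± 3.46 (exact permutation, adjusted p = 0.06 for both). In this score comparison, added after the data were seen, 0 of 18 lists passed the exact permutation test and 5 had an unadjusted p under 0.05. There were 5 lists that passed at equal list length: cDC1 genes were higher in migDC1 (9.03), and cDC2 (-5.94), MHC class II (-2.59) and tolerance-associated genes (-3.47) and monocyte and macrophage markers (-12.65) lower (exact permutation, adjusted p = 0.036 each).

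For loss of Ifngr1 in CD11c-expressing cells, no region passed the test. A region that alone separated the genotypes completely could not have passed either, so changes at very few regions are not excluded. Across all 14 Cre-positive and 14 Cre-negative libraries, the exact conditional test with subset as strata called 0 of 61445 regions, with 170 at an unadjusted p under 0.05 (70 more and 100 less often called in Cre-positive libraries) and a smallest adjusted p of 0.512. That region lies in Mid1, a ubiquitin ligase gene of the X chromosome (169977786 to 169980571), and was called in 1 of 14 Cre-positive and 14 of 14 Cre-negative libraries (exact p = 8.33e-06). Among the always-given genes, the smallest p belonged to a region of Itgam (chromosome 7, 128115174 to 128115929, 14 of 14 Cre-positive and 6 of 14 Cre-negative libraries, exact p = 0.00333, adjusted p = 1). The next was a region of Irf8 (chromosome 8, 120711072 to 120711989, 8 of 14 and 14 of 14 libraries, exact p = 0.005, adjusted p = 1). An Xist region was called in 14 of 14 Cre-positive and 4 of 14 Cre-negative libraries (exact p = 0.000533, adjusted p = 1). The labels do not give the sex of the mice, which therefore stays open in every genotype comparison. A Socs1 region was called in 8 and 11 libraries, a Cd274 region in 8 and 11 and an Irf1 region in 5 and 9.

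No list had a region that passed, adjusted over all regions or over the list alone. At an unadjusted exact p under 0.05 there were 1 rising and 1 falling region of maturation genes, 1 falling region each of tolerance-associated and cDC1 genes, 3 rising regions of cDC2 genes and 1 rising region of Langerhans and skin DC genes. There were 0 in the other lists. By score, IFN-γ-induced genes were lower in Cre-positive libraries, 1.05 ± 7.13 against 2.99 ± 7.16 (SD, n = 14 each), an effect of -1.88 within subsets that did not pass (exact permutation p = 0.0143, two-sided; adjusted p = 0.257). The difference was negative in 5 of 5 subsets: -2.87 in cDC1, -1.47 in cDC2, -1.19 in migDC1, -3.32 in migDC2 and -0.55 in DN migDC. The Xist counts of 14 and 4 are from the same sets of libraries. Within plain numbered titles it was -2.19 (exact p = 0.0175), and without the third Cre-positive DN migDC library it was -2.17 and passed (exact p = 0.00259, adjusted p = 0.0466). At equal list length it was -1.54 (exact p = 0.0221), and with regions at gene ends only it was -0.54 (exact p = 0.691). Type I IFN genes differed by -2.27 (exact p = 0.0423, adjusted p = 0.336) and the IFN-γ pathway by -0.65 (exact p = 0.456, adjusted p = 0.911). Such agreement over subsets was not particular to IFN-γ-induced genes. Type I IFN genes were also lower in 5 of 5 subsets, and cDC1 genes (effect 0.31) in 0 of 5. Genes of the cDC2 list differed by 1.78 (exact permutation p = 0.056, adjusted p = 0.336). By exact permutation of the difference in effect between migratory and resident cells, 0 lists passed and 1 had an unadjusted p under 0.05. That was the list of tolerance-associated genes (-2.62, exact p = 0.0363, adjusted p = 0.653).

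In the germline cohort, where an exact permutation of 2 against 2 libraries cannot go under 0.05, IFN-γ-induced genes scored 6.7 and 8.45 in WT and 1.54 and 6.42 in KO migDC2, a mean difference of -3.6. The largest difference was that of B cell markers, -9.63, and NK and ILC markers differed by -3.97. Type I IFN genes differed by -3.15, MHC class I genes by -7.77 and the IFN-γ pathway by 0.07, and 12 of 18 lists differed in the same direction as in the floxed cohort. Of the 70 regions more often called in Cre-positive libraries at an unadjusted p under 0.05, 64 showed no germline difference, 5 the same and 1 the opposite direction; of the 100 less often called, 95, 4 and 1. Most of them, 52 of the 70 and 92 of the 100, had no call in any germline library, so a difference could not be seen there. Libraries of the same genotype were not more alike than others of their subset, with a mean Jaccard difference of -0.0162 (exact permutation, one-sided p = 0.984, two-sided p = 0.0858).

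Regions more often called in Cre-positive libraries gathered at Itgax, the gene of CD11c (chromosome 7, 128129526 to 128150657). Within 100 kb on either side, 29 of 38 tested regions were called in more Cre-positive libraries and 3 in fewer, and 11 of the 70 such regions of the genome at an unadjusted p under 0.05 lay here. On average 47.7 ± 15.9% of the 38 regions were called in Cre-positive and 25.2 ± 11.7% in Cre-negative libraries (SD, n = 14 each), a difference within subsets of 21.8 percentage points. Its exact permutation p was 2.08e-06 (two-sided), the smallest possible, in a window chosen after the data were seen. Among 1608 consecutive windows of 38 tested regions, the plain difference of shares was as large as here (22.6) in 1 other, on X at 48523454 to 50623473 (23.5). There 18 of the 38 regions lay in Firre, a noncoding RNA gene. The difference was positive in 5 of 5 subsets, from 10.5 in migDC1 to 33.3 in cDC2. Regions of Itgax (128127729 to 128128276, 12 of 14 against 1 of 14 libraries) and of its neighbour Itgad (128177663 to 128178923, 10 against 1) are examples. In the germline cohort, which carries no Cre, 36 of the 38 regions had no call in any of the 4 libraries, so a difference could not be seen there.

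**Figure D3:**
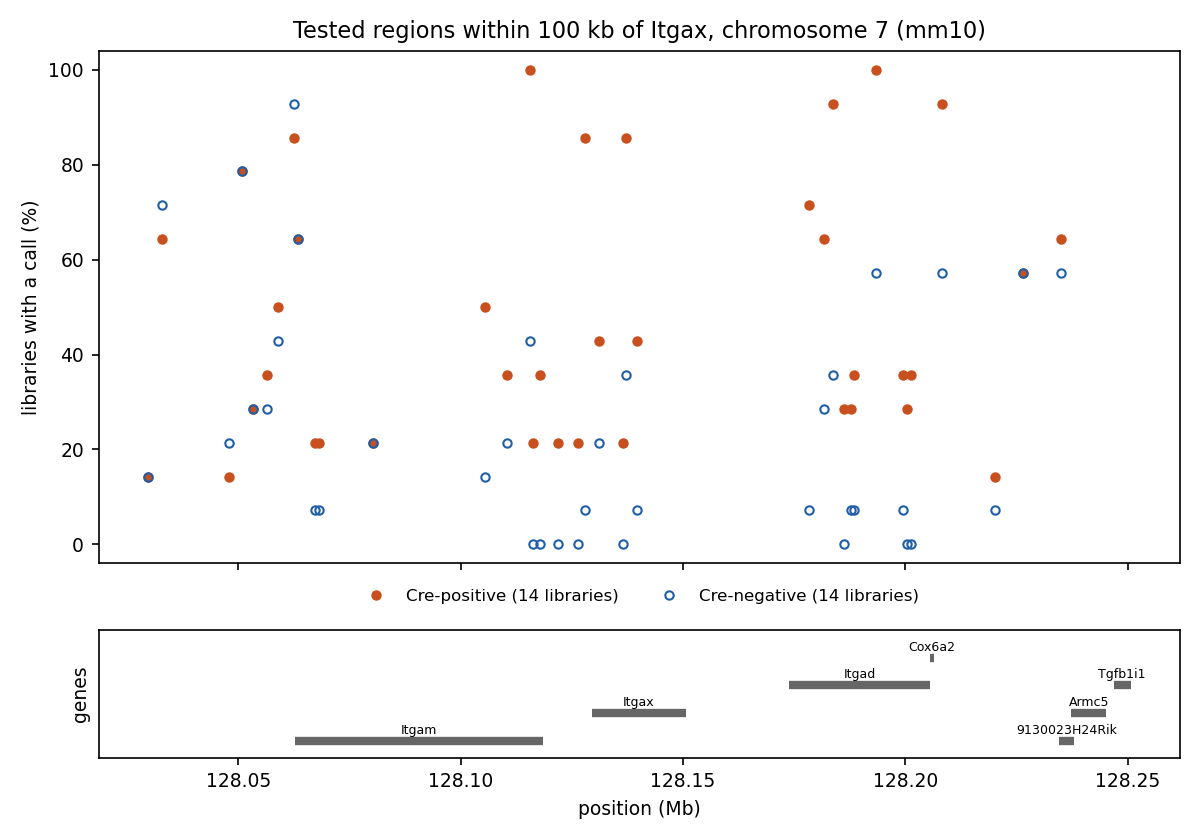
Percent of 14 Cre-positive (filled) and 14 Cre-negative (open) floxed libraries with a call, for each tested region within 100 kb of Itgax by its position on chromosome 7 (mm10, Mb), with the genes of the window as bars underneath. Cre-positive libraries have more calls in 29 of the 38 regions.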

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

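The alternatives without the DN migDC libraries, on the autosomes without the 1 Mb around Itgax, and of list enrichment at equal list length were chosen after seeing the data, as were enrichment in single-subset comparisons, title series as strata and all score comparisons between pairs of subsets. The exact genotype test called 0 regions under each alternative (8 to 445 at an unadjusted p under 0.05) and with each library left out. In resident or migratory subsets alone the smallest exact p was 0.005 or 0.000833. Such values pass the adjustment only when many regions change, so the 0 there says little. Migratory against resident gave 21551 to 32894 calls at equal list length, with other overlaps, without the filter and in bins of 500 bp, and 21955 without DN migDC. It gave 12925 with the stronger part of each list, 9776 and 10140 in Cre-negative and Cre-positive libraries alone and 10859 within plain numbered titles, which have fewer regions or libraries by construction. For cDC2 against cDC1 there were 8100 calls at equal list length, 2396 with the stronger part of each list and 0 in bins. For migDC2 against cDC2 there were 7043 with the stronger part and 0 within plain numbered titles, where 2 against 6 libraries cannot pass. For migDC1 against cDC1 there were 7132 with the stronger part, and for migDC1 against migDC2 3534 at equal list length. Where list length or bins moved a count, the cause was not tested.

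Leaving out each library in turn gave 21587 to 26833 calls for migratory against resident, 4907 to 12558 for cDC2 against cDC1 (12081 without cDC1 Cre-negative 2 and 12558 without cDC1 Cre-positive 2). It gave 13732 to 15362 for migDC2 against cDC2, 0 to 15116 for migDC1 against cDC1 (0 without any 1 of the 4 migDC1 libraries) and 0 for DN migDC and for migDC1 against migDC2. The difference in peaks ranged from -2258.2 to 811.0 for genotype and from 4998.8 to 8338.3 for migratory minus resident, and the Jaccard difference from -0.028 to 0.0059. The number of list scores past the threshold ranged from 0 to 1 for genotype (1 without DN migDC Cre-positive 3, where IFN-γ-induced genes had -2.17, exact test, adjusted p = 0.0466), from 11 to 12 for migratory minus resident, and it was 0 for the difference of genotype effects.

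Peaks at or above the pooled median signal numbered 4973.9 more in migratory libraries (exact p = 0.00813), past the threshold, and the cause was not tested. Total bp covered (1274895.8 more, exact p = 0.603) and peaks within plain numbered titles (10002.8 more, exact p = 0.11) did not pass. With lists of equal length 16 list scores gained and 7 lost their call. Enriched lists and directions at equal list length were 2 for migratory against resident (1 with full lists) and 3 for migDC2 against cDC2 (0 with full lists); the cause was not tested. Reversals were the Socs2 region on chromosome 10 at 95357720 within plain numbered titles (8.3 points, exact p = 1), and the scores of the IFN-γ pathway (-0.35) and of ubiquitously active genes (2.18) with regions at gene ends only; the cause was not tested. Of 221 named regions 166 passed or failed as before at equal list length and 55 lost their call. Within plain numbered titles 45 of 110 passed or failed as before, 64 lost their call and 1 reversed.

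Title numbers were tested as a replicate block in the migratory subsets. Correlations of same-numbered libraries ran from -0.002 to 0.108, which gave no sign that the numbers pair the samples. Each value rests on few lettered libraries per group, so pairing is not excluded. With the block 0 regions passed for DN migDC against migDC2 (320 at an unadjusted exact p under 0.05, smallest p allowed 0.0312) and 0 for migDC1 against migDC2 (smallest p allowed 0.125). For migDC1 no region could have passed, and for DN migDC only if most regions had separated, so the block tests little. The motif test and both of its alternatives were not run. Since depth is unknown, weak open regions absent from short lists cannot be told from closed ones.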

Other observations

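Tests chosen only after the result was seen were those of the Itgax window and of transgene copies there, of longer lists and of title series behind the migratory calls, and of the B cell score between DN migDC and migDC2, like all scores between pairs of subsets, and unadjusted counts in splits for the lineage comparisons. The mean B cell score was highest in DN migDC, and whether its difference from migDC2 passed depended on the strata. It was 0.66 ± 10.07 in DN migDC and -18.49 ± 9.02 in migDC2 (SD, n = 6 each; exact permutation p = 0.015, adjusted p = 0.054), and it passed without the first Cre-negative migDC2 library (effect 22.0, exact permutation, adjusted p = 0.045). With title series as strata it passed (19.15, exact permutation, adjusted p = 0.0214), with title series and genotype as strata it lay at the threshold (adjusted p = 0.05), and at equal list length with genotype as strata it did not pass (4.67, adjusted p = 0.135). Pax5, the transcription factor of B cell identity, had 13.5 ± 2.88 of its 20 regions called in DN migDC, 9.67 in migDC2, 9.5 in migDC1, 5.67 in cDC1 and 2.5 in cDC2. Ms4a1, encoding CD20, had 1.83 of its 3 regions called in DN migDC and 2.0 in cDC1. The score was 9.83 in plain-titled and -3.92 in lettered DN migDC libraries, and -8.03 and -23.72 in those of migDC2.

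In the Mid1 gene body, neighbouring regions of the X chromosome at 169977786 to 169980571 and 169980748 to 169982364 were called in 1 and 0 of 14 Cre-positive libraries and in 14 and 11 of 14 Cre-negative ones, while the next region, at 169983066 to 169984154, was called in 0 and 3. The one after it, at 169984228 to 169988001, was called in all of both. On a scaffold without a chromosome, JH584304, the longest peak spanned 13238 to 52310 bp in plain-titled, 2316 to 6645 bp in lettered and 4720 to 6656 bp in germline libraries.

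Regions around Itgax were called more often in Cre-positive libraries by 21.8 percentage points. Longer lists are argued against, since the difference at equal list length was 14.6 points (exact permutation p = 4.17e-06). Extra copies from a Cre transgene built from the Itgax locus are a candidate explanation. The germline cohort, which carries no Cre, does not test it, since 36 of the 38 regions had no call in any germline library. Loss of Ifngr1 goes with Cre in each floxed library, so the transgene and the loss cannot be told apart here.

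An Xist region (X, 103481098 to 103482421) was called in 14 of 14 Cre-positive and 4 of 14 Cre-negative libraries (exact p = 0.000533, adjusted p = 1), and 5 regions of Firre, a noncoding RNA gene of the X, were called in the same libraries. List length is argued against, because at equal list length the Xist region was still called in 10 more Cre-positive than Cre-negative libraries. The share of X regions called, minus that of autosomal regions, was higher by 1.74 points in Cre-positive libraries (exact permutation p = 0.0869, two-sided). That share is taken over 1708 X regions, so it cannot decide on a pattern seen at few of them. A different sex makeup of the mice could give this pattern and stays open. The lists hold no peaks on Y to check it, so sex and genotype cannot be told apart for these regions. The same libraries enter every genotype comparison, that of IFN-γ-induced genes and the Itgax window included. In the germline cohort the region was called in 1 of 2 KO and 1 of 2 WT libraries.

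More regions were called more often than less often in migratory libraries, 62.3% of calls. Title series is argued against as the whole cause of the rising calls: of rising regions selected with 12 lettered migratory and 8 resident libraries, at least 95.1% were also called more often in the 4 plain-titled migratory than in the 4 other resident libraries, whichever resident replicate was left out. Other splits of those 8 libraries reached 92.0%. For falling calls the lowest such share was 72.6% (another split 73.1%), so title series and migration cannot be told apart there. Longer lists may account for the excess of rising calls, since at equal list length 45.7% rose, while the calls themselves numbered 21551. Whether migratory cells have more open regions is therefore not settled by these lists.

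Other splits of the libraries within strata were tested for each comparison, 100 splits each with the real one included. For migratory against resident no other split gave as many calls (24643 calls, highest other split 3807, 1 of 100 as large, the smallest share possible). For single subsets, regions at an unadjusted exact p under 0.05 were counted, since the adjusted count is 0 unless very many regions separate. By these, no other split drawn gave as many for cDC2 against cDC1 (9799, highest other 2604), migDC2 against cDC2 (13511, 1436) or migDC1 against cDC1 (17560, 3666). The same held for DN migDC against migDC2 (1377, 714) and migDC1 against migDC2 (6400, 1756), where 0 regions passed the adjustment. In each comparison 1 of 100 was as large, the smallest share possible, so a chance split of these libraries is argued against at that share only. Chance cannot be excluded for genotype: 65 of 100 splits gave as many as its 170 regions, and the highest other gave 2179, several times as many, which points to a structure of the libraries within subsets that was not identified here.

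Within single subsets, regions called in 3 of 3 libraries of one genotype and 0 of 3 of the other numbered 184 in cDC1 (highest other split 2379), 50 in cDC2 (2013), 260 in migDC2 (1007) and 194 in DN migDC (1022). With 10 splits of 3 against 3 libraries, of which 7, 7, 7 and 9 gave as many, the splits are too few for a share under 0.05. Chance alone separates 10% of regions called in 3 of 6 libraries in a given split.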
